A study of Mus musculus with 5 samples.

How the data were processed

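BRG1 ChIP-seq was made from bone marrow-derived macrophages of WT and Baf60a KO mice with or without oxLDL. Per the labels' protocols, chromatin was prepared with an enzymatic ChIP kit (SimpleChIP), so fragment ends follow nuclease cuts, and was precipitated with an Abcam antibody against BRG1. Libraries were made with the NEBNext Ultra II FS kit and sequenced as paired ends on a NovaSeq. The dose and duration of oxLDL and the sex and number of mice are not given in the sources used here. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie2, MACS3 and mm10, without parameters or roles. Whether the input library served as the control of the peak caller is not given in the sources used here, and the input was not analysed here. Groups were taken from the sample titles, with 1 library each for WT, KO, oxLDL WT and oxLDL KO.

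The authors deposited 1 peak list per library, so peaks were called per library and not on pooled samples. For each peak the deposited lists give a score, which is 10 times the −log10 q cut to a whole number. The deposited fold enrichment is a ratio of the pileup to the local background at the summit. The authors also gave −log10 p and −log10 q values, which were used as deposited, and the summit position, an offset in bp from the peak start. The lowest −log10 q was 1.02, 1.07, 1.01 and 1.01 in WT, KO, oxLDL WT and oxLDL KO, and the lowest −log10 p was 5.13, 5.33, 3.67 and 3.96. A longer list has a lower p limit at the same q limit, so list lengths were also compared at a −log10 p of at least 5.33 in all 4. All peaks lay on chromosomes 1 to 19, and why none lay on X or Y is not known. Genes on X and Y stay in the gene totals and gene lists, where they count as having no peak. No peaks of 1 list overlapped each other.

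A peak list holds no read totals. Taking a pseudocount of 1, the deposited fold enrichment is (pileup + 1)/(background + 1), and the p-value is the Poisson tail of the pileup given the background. Both were solved for the pileup and the background of each peak. The pileup came out as a whole number, within 2% of the step in −log10 p between neighbouring whole pileups, for 99.6% of peaks in WT, 97.1% in KO, 99.99% in oxLDL WT and 99.96% in oxLDL KO. The lowest background of a list was taken as the level set by the whole library, which scales with the number of fragments and their length. Divided by the smallest peak width it was 1.27, 1.69, 1.60 and 1.56 fragments per 100 bp. High-background peaks, with a background over 5 times the lowest of their list, were defined after the values had been seen.

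Overlap meant at least 1 bp shared, and was counted as the share of each list with a counterpart in the other. Random overlap came from 1000 placements of the other list on the same chromosomes, from position 3 Mb to the last gene end. The share of gene-end positions expected at random came from 200000 draws over the same span. Peaks were ranked by fold enrichment within their own list and split into quintiles, and the odds ratio of being overlapped at gene ends against elsewhere was pooled over quintiles by the Mantel-Haenszel method. Gene positions came from a table of RefSeq genes on GRCm38.p6, the assembly of mm10, with 21883 protein-coding genes. This table has gene starts and ends without strand, exons or transcripts. The design fixed before the data were examined used promoters, within 1 kb of a transcription start, and this was replaced by gene ends, within 1 kb of either end of a protein-coding gene. A gene body therefore holds both exons and introns. A summit within 1 kb of 2 neighbouring genes counts for both.

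The 25 gene lists were fixed before the data were examined: 11 pathways, 6 other tissues or cell types, and 8 gene families taken by symbol pattern. Of the symbols in the lists, 2 (Mx1 and Mx2) did not match a protein-coding gene. For each list, the number of genes with a gene-end peak was set beside 10000 random lists of the same size from all protein-coding genes, and its percentile, with ties shared evenly, describes that library. Matching on promoter GC content was planned and was not run, since no genome sequence was used here. Searches for transcription factor motifs at summits were not run for the same reason. Some genes, such as Ctsb, Ctsd, Atf3, Psmb8 and Psmb9, stand in more than 1 list.

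The rule for named peaks and genes was fixed before the data were examined. It takes, for each comparison and list, the 10 peaks with the highest fold enrichment among those overlapped in the other list and the 10 among those not overlapped. Each is named by a protein-coding gene with an end within 1 kb of the summit, else the gene that holds it, else the nearest gene end within 100 kb. A peak called near a gene can thus lie up to 100 kb from it, and the name does not show that the peak acts on that gene. For each gene list it takes up to 4 genes with gene-end peaks in both oxLDL lists and up to 4 with one in a single list, by fold enrichment, some of which are printed. Smarcd1 and Smarca4 were added. Some genes that the rule names are not reported here. Genes outside this rule, such as Jund, were named after their values had been seen.

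With 1 library per group, no test between conditions was made. Shares carry Wilson 95% intervals. They cover counting error over peaks only, and fragments without molecular identifiers are not independent molecules. Alternatives were a −log10 q of at least 5, overlap of at least 50% of both peaks, summits within 200 bp, lists of equal length, gene ends within 2 kb, all contigs and unmerged lines. Alternatives added after seeing the data were a common p limit, lists without high-background peaks, random lists matched on gene length, and gene bodies counted with gene ends.

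Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. They were tested on simulated data. The recovery of pileups returned the simulated values for 100% of 2000 peaks with a base background near the lowest of WT. It did so for 100% of 2000 with a base near the lowest of oxLDL WT. Simulated backgrounds ran up to 10 times the base, well below the median of 624 fragments at high-background WT peaks. The same formula made and solved these peaks, so the assumed pseudocount was not tested. A planted overlap of 19.8% of 237 peaks was found as 19.8% for WT by KO, and one of 20.0% of 9907 peaks as 20.1% for oxLDL WT by oxLDL KO. Of random gene lists over 21883 genes, 4% (oxLDL WT) and 2.5% (oxLDL KO) reached percentile 97.5, and of lists with 10 of 30 genes planted, 100% did in both.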

Results

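Binding of BRG1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in macrophages grown from the bone marrow of Baf60a knockout (KO) and wild-type (WT) mice, with and without oxidised low-density lipoprotein (oxLDL). BRG1, encoded by Smarca4, is an ATPase of the SWI/SNF chromatin remodelling complexes, which move nucleosomes. BAF60a, encoded by Smarcd1, is an accessory subunit of these complexes. Macrophages take up oxLDL through scavenger receptors and become lipid-loaded, as in the artery wall in atherosclerosis. The series holds 5 libraries: 1 input without antibody, and 1 BRG1 library each of WT, KO, oxLDL WT and oxLDL KO cells. Peak lists of the 4 BRG1 libraries were analysed, 1 list per library. With 1 library per group there is no replicate check, no difference between lists can be set against a spread between replicates, and no p-value is given. Intervals on shares are Wilson 95% intervals and cover counting error only. Fold enrichment over local background is the authors' own value for each peak and is used to describe and rank peaks within a list. Positions are on mm10.

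Smarcd1 (chromosome 15, 99702287 to 99713995), the targeted gene, had no peak in its body or within 1 kb of it in any of the 4 lists, and a BRG1 peak list does not show whether the gene was deleted. Smarca4 (chromosome 9, 21616106 to 21704230) had 1 peak, in the oxLDL WT list, with its summit at 21616489 and a fold enrichment of 3.19.

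Peak lists differed in length by more than an order of magnitude. The authors' caller listed 237 peaks in WT, 139 in KO, 9907 in oxLDL WT and 4668 in oxLDL KO. The peaks covered 77.7, 49.0, 4653 and 1734 kb, with median widths of 268, 282, 368 and 309 bp. Total read numbers are not known from peak lists. The fragment pileup and the local background behind each peak could be recovered from its fold enrichment and p-value, and the lowest background of a list served as a measure of relative depth. It was 2.70 fragments in WT, 3.84 in KO, 3.76 in oxLDL WT and 3.42 in oxLDL KO. A median peak rested on a pileup of 16, 22, 17 and 17 fragments. Some peaks lay where the local background was over 5 times the lowest of the list, and these are called high-background peaks here. They numbered 51 in WT (21.5%), 48 in KO (34.5%), 58 in oxLDL WT (0.585%) and 83 in oxLDL KO (1.78%). Of these, 29, 28, 28 and 29 lay before position 3.1 Mb of chromosome 9.

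With all deposited peaks counted, BRG1 peaks lay at gene ends more often than random positions did. A summit counted as a gene-end peak when it was within 1 kb of either end of a protein-coding gene, since the annotation used gives no strand and the 5′ and 3′ ends cannot be told apart. This share was 19.8% in WT (interval 15.3 to 25.4), 21.6% in KO (15.6 to 29.1), 32.2% in oxLDL WT (31.3 to 33.1) and 38.7% in oxLDL KO (37.3 to 40.1), against 3.03% of random positions. Summits inside genes made up 35.9%, 26.6%, 41.8% and 37.7%, against 39.4% of random positions, and 44.1%, 37.4%, 42.0% and 38.1% without high-background peaks. Without them, the gene-end share was 25.3% in WT, 33.0% in KO, 32.4% in oxLDL WT and 39.4% in oxLDL KO. In both genotypes, the difference in this share between untreated and oxLDL-treated cells therefore rests in part on these peaks. At a −log10 q of at least 5, the share was 29.4% in oxLDL WT and 36.3% in oxLDL KO, but 2.90% of the 69 peaks left in WT and 3.64% of the 55 in KO, of which 45 and 42 were high-background peaks. At that limit the untreated lists as a whole show no excess at gene ends. Their gene-end peaks then lay at 2 genes in each list, too few to show whether the peaks outside high background have an excess.

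**Figure D1:**
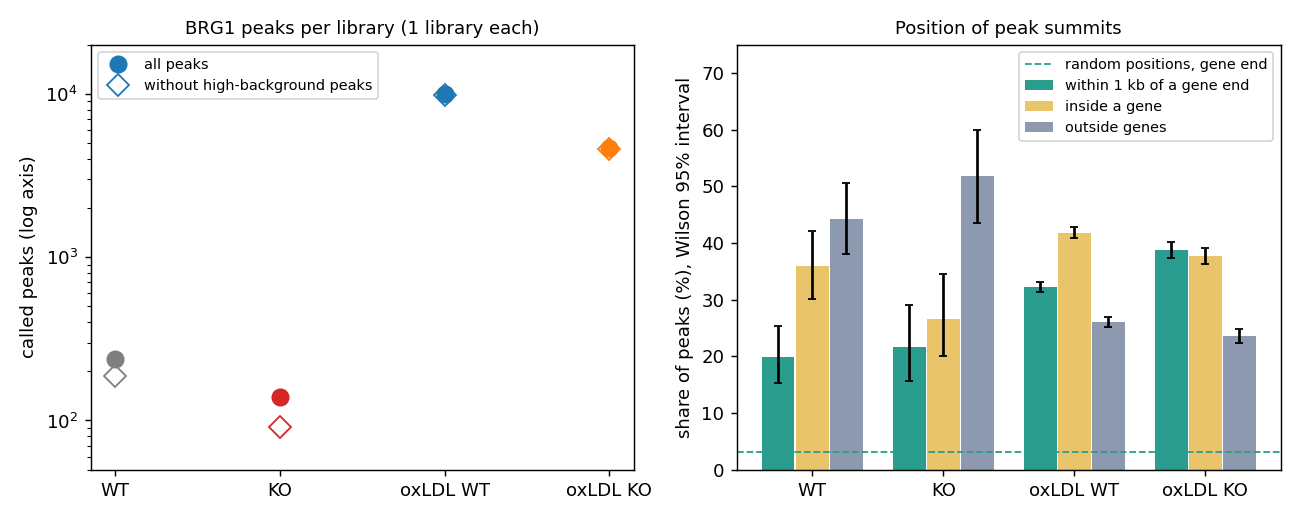
Called BRG1 peaks per library (left, log axis; filled circles, all peaks; open diamonds, without high-background peaks) and the share of summits within 1 kb of a gene end, inside a gene or outside genes (right, in percent, bars with Wilson 95% intervals; the dashed line marks the 3.03% of random positions at gene ends). The oxLDL libraries hold 9907 and 4668 peaks and the untreated ones 237 and 139.

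The first comparison, KO against WT under oxLDL, asks how BRG1 binding in lipid-treated macrophages differs without BAF60a. Fewer BRG1 peaks were called in the knockout: 4668 in oxLDL KO and 9907 in oxLDL WT, a ratio of 0.471, and the ratio of the covered lengths was 0.373. Genes of the macrophage lineage carried gene-end peaks in both libraries, among them Spi1, which encodes the lineage-determining factor PU.1, and Tyrobp, which encodes the signalling adaptor DAP12. Gene-end peaks were found at 3259 protein-coding genes in oxLDL WT and at 1918 in oxLDL KO. Both lists shared 1309 of these genes, 40.2% of those in oxLDL WT and 68.2% of those in oxLDL KO, where independent lists of these sizes would share 286. At 1119 of the 1309 shared genes (85.5%, interval 83.5 to 87.3), the highest oxLDL WT peak at a gene end overlapped an oxLDL KO peak.

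Among the gene lists fixed before the data were examined, macrophage lineage genes had the highest share with a gene-end peak in both libraries. Of 26 such genes, 22 had a gene-end peak in oxLDL WT and 12 in oxLDL KO. Random lists of the same size had a median of 4 and 2 such genes, and both counts lay above all 10000 random lists. High percentiles were not particular to this list. Of the 11 pathway lists, 10 in oxLDL WT and 9 in oxLDL KO lay at or above percentile 97.5. Random lists were drawn from all protein-coding genes, including families with almost no peaks, such as olfactory receptors. The top rank of the macrophage list in oxLDL KO depends on the limit. At a −log10 q of at least 5, its share was 26.9% in oxLDL WT and 0% in oxLDL KO. In oxLDL WT this was still the highest of the 11 pathway lists, followed by the AP-1 list at 23.1%. In oxLDL KO the inflammatory list then had 8.82% and the AP-1 list 7.69%. The unfolded protein, interferon and cell cycle lists also had 0% in oxLDL KO at that limit. With all peaks, gene-end peaks of both libraries were found at 11 of the genes. Paired values here and below are the highest gene-end peak of each library and need not come from the same site. Spi1 (chromosome 2, 91082374 to 91115759) had a highest gene-end fold enrichment of 5.02 in the oxLDL WT list and 4.10 in the oxLDL KO list. These 2 peaks did not overlap, and the oxLDL KO peak that overlapped the oxLDL WT one had 3.61. Further inside Spi1, overlapping peaks had 4.58 in oxLDL WT and 4.67 in oxLDL KO, the highest oxLDL KO value in the gene. Mpeg1, which encodes the pore-forming protein perforin-2, had 4.41 and 3.62, and the transcription factor gene Maf had 3.90 and 4.34. At Tyrobp (3.78 and 4.53) the highest summits of the 2 libraries lay at opposite ends of the gene. A gene-end peak in oxLDL WT alone was found at 11 genes, led by Fcer1g, the Fc receptor gamma chain, at 5.25. Others were Coro1a, which encodes the actin-binding protein coronin 1A, at 4.81, and Fcgr1, the high-affinity IgG receptor, at 4.62. None of these 3 had an oxLDL KO peak in the gene body either.

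Of 34 genes of lipid uptake, efflux and storage, 16 had a gene-end peak in oxLDL WT and 10 in oxLDL KO (random medians 5 and 3, percentiles 100 and 99.98). These shares, 47.1% and 29.4%, became 64.7% and 52.9% with gene bodies counted. At a −log10 q of at least 5 they were 8.82% and 2.94%. Genes with peaks in both libraries included Npc1 (3.19 in oxLDL WT and 4.98 in oxLDL KO) and Npc2 (4.20 and 3.17), whose products move cholesterol out of lysosomes, the nuclear receptor gene Pparg (3.45 and 4.24) and the acyl-CoA synthetase gene Acsl1 (2.78 and 3.76). A gene-end peak in oxLDL WT alone was found at Plin2, which encodes a lipid droplet coat protein (5.25), at Scarb1, the receptor for high-density lipoprotein (4.62), and at the cholesterol efflux transporter gene Abcg1 (3.99). Plin2 and Abcg1 had an oxLDL KO peak inside the gene. The lipid list held 6 genes with gene-end peaks in both libraries, 10 in oxLDL WT alone and 4 in oxLDL KO alone.

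Of 34 inflammatory cytokine and NF-kB pathway genes, 13 had a gene-end peak in oxLDL WT (percentile 99.93) and 5 in oxLDL KO (percentile 87.9). Both libraries shared 2 of them, the Toll-like receptor adaptor gene Myd88 (3.99 and 5.20) and Nfkbia, which encodes the NF-kB inhibitor IkB-alpha (4.06 and 3.62). Peaks at Rel, an NF-kB subunit gene, and Tlr4, the receptor for bacterial lipopolysaccharide, were in oxLDL WT alone, both with a fold enrichment of 5.56. Nfkb1 (5.52) and the inflammasome gene Nlrp3 (5.20) had gene-end peaks in oxLDL KO alone, and Nlrp3 had an oxLDL WT peak inside the gene. At a −log10 q of at least 5, the share of the inflammatory list was 8.82% in both libraries. Its difference between the libraries therefore rests on peaks below that limit. Interferon response genes counted 11 of 29 in oxLDL WT (percentile 99.9) and 4 in oxLDL KO (percentile 82.9), all 4 of them shared: Irf5 (4.62 and 4.07), the interferon receptor gene Ifnar2 (4.60 and 4.22, with the highest summits at opposite ends of the gene), and the antigen-processing genes Psmb9 and Tap1, which share 1 peak between them (4.20 and 3.85). Ifih1 (4.41), Irf2 (4.33), Ifnar1 (4.06) and Gbp3 (3.99) had one in oxLDL WT alone, and Irf2 had an oxLDL KO peak inside the gene.

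With all peaks counted, stress-response lists were represented in both libraries. Of 29 genes of the NRF2 and oxidative stress response, 14 had a gene-end peak in oxLDL WT and 9 in oxLDL KO (percentiles 100 and 99.98). They included the superoxide dismutase gene Sod1 (3.36 and 5.20), Osgin1 (4.83 and 4.30), Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis (4.59 and 3.85), and Bach1, a repressor of antioxidant genes (3.55 and 4.40). Nfe2l2, which encodes NRF2 itself (4.62), Gpx1 (3.78) and Keap1, which encodes the NRF2 inhibitor (3.77), had a gene-end peak in oxLDL WT alone, and Taldo1 (3.76) in oxLDL KO alone. Nfe2l2 had an oxLDL KO peak inside the gene, and Taldo1 an oxLDL WT peak. Of 26 genes of the unfolded protein and integrated stress response, 13 and 6 had one (percentiles 100 and 98.6). The sensor gene Ern1 (4.62 and 4.30) and Atf3 (4.20 and 2.94) were in both, and Xbp1 (4.41) and Ddit3 (4.17) in oxLDL WT alone. The unfolded protein list held 9 genes in oxLDL WT alone and 2 in oxLDL KO alone. Of 26 AP-1 and immediate early genes, 17 and 11 had one, above all random lists in both libraries. Jun (4.79 and 3.32), Fosl2 (4.49 and 4.58) and Klf2 (2.59 and 5.43) were in both, and Klf4 (4.84) and Ier3 (4.41) in oxLDL WT alone. The AP-1 list held 7 genes in oxLDL WT alone and 1 in oxLDL KO alone.

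Lysosome and autophagy genes counted 16 and 9 of 35 (percentiles 100 and 99.8), with the cathepsin genes Ctsz (6.09 and 3.40) and Ctsd (4.20 and 3.40) in both and Ctsl (4.44) in oxLDL WT alone. Of this list, 10 genes were in oxLDL WT alone and 3 in oxLDL KO alone. Among the latter was Ctsb (4.10), which had an oxLDL WT peak inside the gene. Paired values need not come from the same site: the highest Ctsz summits lay at 174439825 in oxLDL WT and 174438123 in oxLDL KO. The NRF1 and mitochondrial biogenesis list had 7 of 32 genes in each library (percentiles 85.9 and 98.7), of which 4 were shared: the mitochondrial transcription factor gene Tfb2m (3.78 and 7.01), Esrra (4.41 and 6.34), Polg2 (3.55 and 4.07) and Nrf1 (4.03 and 3.82). Another 3 genes were in oxLDL WT alone and 3 in oxLDL KO alone, the latter including Tomm70a (4.53) and Pink1 (4.30). SWI/SNF subunit genes counted 9 and 8 of 28 (percentiles 98.9 and 99.9, and 95.3 in oxLDL WT against random lists matched on gene length), with Bicra (5.25 and 3.39), Dpf2 (5.04 and 3.85), Arid2 (3.41 and 4.74) and Brd7 (2.46 and 4.17) in both. The highest Bicra summits lay at 16047689 in oxLDL WT and 16048706 in oxLDL KO. SWI/SNF subunit genes in oxLDL WT alone numbered 3, and those in oxLDL KO alone 2, including Bcl7a (3.85). Cell cycle and DNA replication genes counted 10 and 7 of 34 (percentiles 98.4 and 98.3), with Cdk4 (4.41 and 3.62) and the cell cycle inhibitor genes Cdkn1b (4.41 and 3.39) and Cdkn2c (4.83 and 3.07) in both. The highest Cdkn2c summits lay at 109665883 in oxLDL WT and 109667005 in oxLDL KO. Cell cycle genes in oxLDL WT alone numbered 5, and those in oxLDL KO alone 2.

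Genes of other tissues and cell types had few gene-end peaks. Over the 6 lists, 4 of 120 genes had one in oxLDL WT and 1 of 120 in oxLDL KO. Among all protein-coding genes the shares were 14.9% and 8.76%, so both counts were low, though the pooled counts were not set beside random lists. Each list alone was too short to show a depletion in oxLDL KO. Of 20 hepatocyte, 20 neuron and 20 stromal genes, 0 had one in either oxLDL library. For lists of this size random medians were only 3 and 2, so the 3 lists lay at percentiles 1.99, 1.97 and 2.15 in oxLDL WT but at 7.88, 8.2 and 8.0 in oxLDL KO, within the range of random lists. Lymphocyte genes had 1 of 20 in oxLDL WT, Cd4 at 2.46, and neutrophil genes 1 of 20, Mmp8 at 2.94, and neither list had any in oxLDL KO (percentiles 10.8 and 11.0 in oxLDL WT, 8.13 and 7.88 in oxLDL KO). Erythroid and megakaryocyte genes had 2 of 20, Tal1 (6.71 and 4.88, in both libraries) and Pf4 (3.96, in oxLDL WT alone), at percentiles 28.6 and 31.2. Olfactory receptor genes had 3 and 1 of 1106, where random lists had medians of 165 and 97, vomeronasal receptor genes 2 and 0 of 353, and keratins 0 of 53 in both. Against random lists not matched on gene length, some housekeeping families were near the random medians: cytosolic ribosomal protein genes 13 and 6 of 85 (medians 13 and 7), oxidative phosphorylation subunit genes 12 and 6 of 81 (medians 12 and 7), and histone genes 11 and 6 of 82 (medians 12 and 7). Mitochondrial ribosomal protein genes had 8 and 1 of 77 (medians 11 and 7), and in oxLDL KO lay at percentile 0.360, or 1.77 when matched on gene length. Matched on gene length, histone genes lay at percentiles 99.995 and 99.85 and cytosolic ribosomal protein genes at 97.6 in oxLDL WT. Proteasome subunit genes had 13 of 39 in oxLDL WT (percentile 99.8) and 3 in oxLDL KO (percentile 43.9), with Psmd1 (4.20 and 4.98) in both and Psmd14 (5.04) in oxLDL WT alone.

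Among the 16 lists with at least 5 genes in oxLDL WT, the share of these genes that also had a gene-end peak in oxLDL KO ran from 7.69% for cytosolic ribosomal proteins (1 of 13, interval 1.37 to 33.3) to 66.7% for SWI/SNF subunits (6 of 9, interval 35.4 to 87.9), against 40.2% of all such genes. For the macrophage lineage list it was 11 of 22, and for the inflammatory list 15.4% (2 of 13, interval 4.33 to 42.2). Of the 16 lists, 1 lay outside percentiles 2.5 to 97.5 of random draws from the oxLDL WT genes, the cytosolic ribosomal proteins at percentile 1.19, where chance alone would place 0.8. The inflammatory list lay at percentile 3.50.

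**Figure D2:**
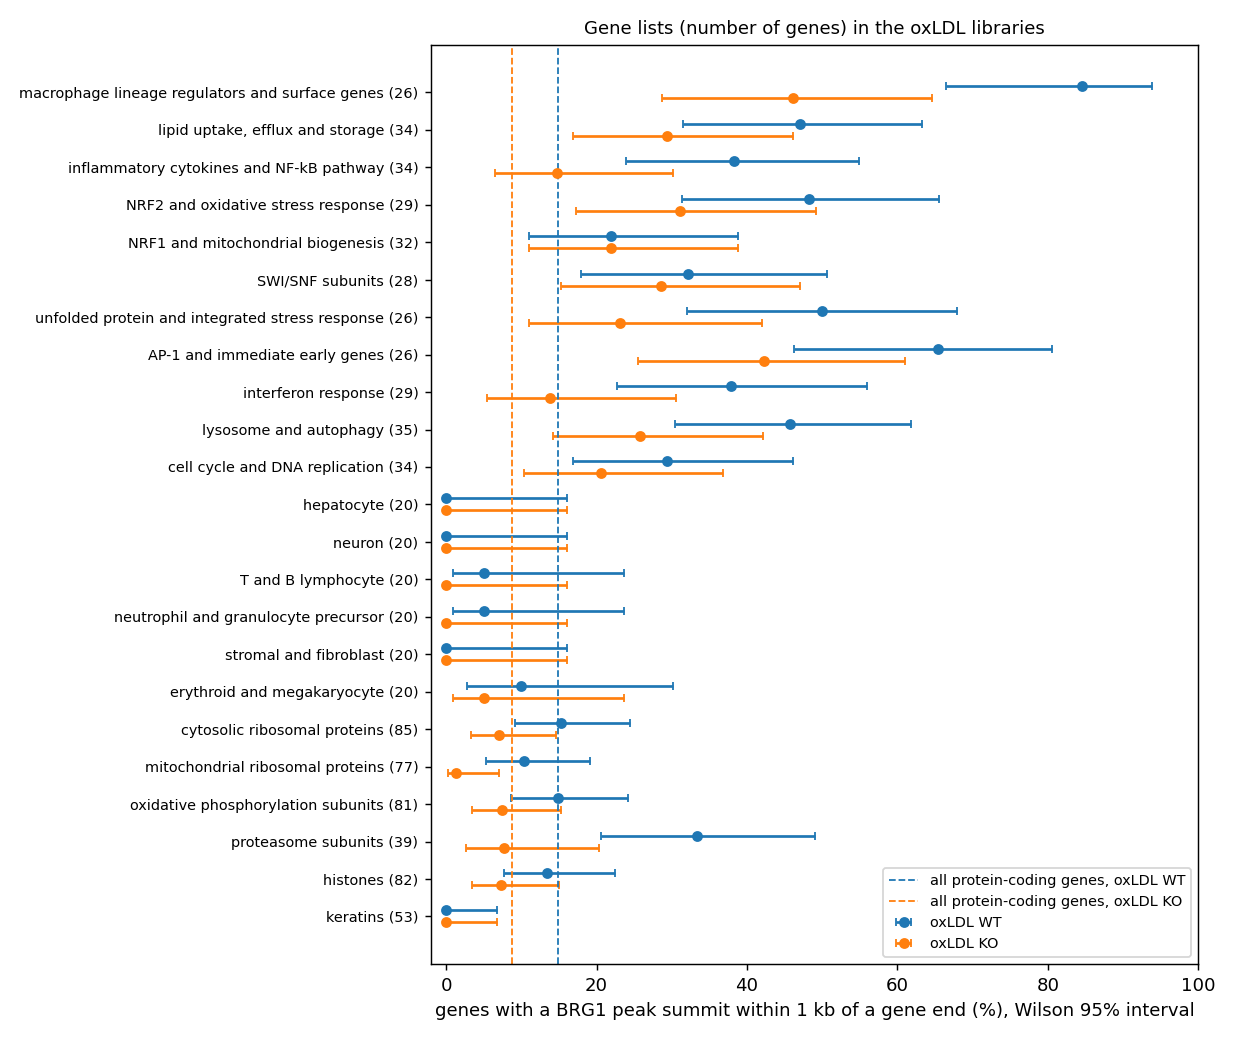
Share of genes in each list (number of genes in brackets) with a BRG1 summit within 1 kb of a gene end, in percent with Wilson 95% intervals, in oxLDL WT (blue) and oxLDL KO (orange); dashed lines give the share among all 21883 protein-coding genes, 14.9% and 8.76%. Macrophage lineage genes reach 84.6% and 46.2%, and hepatocyte, neuron and stromal genes 0%.

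**Figure D3:**
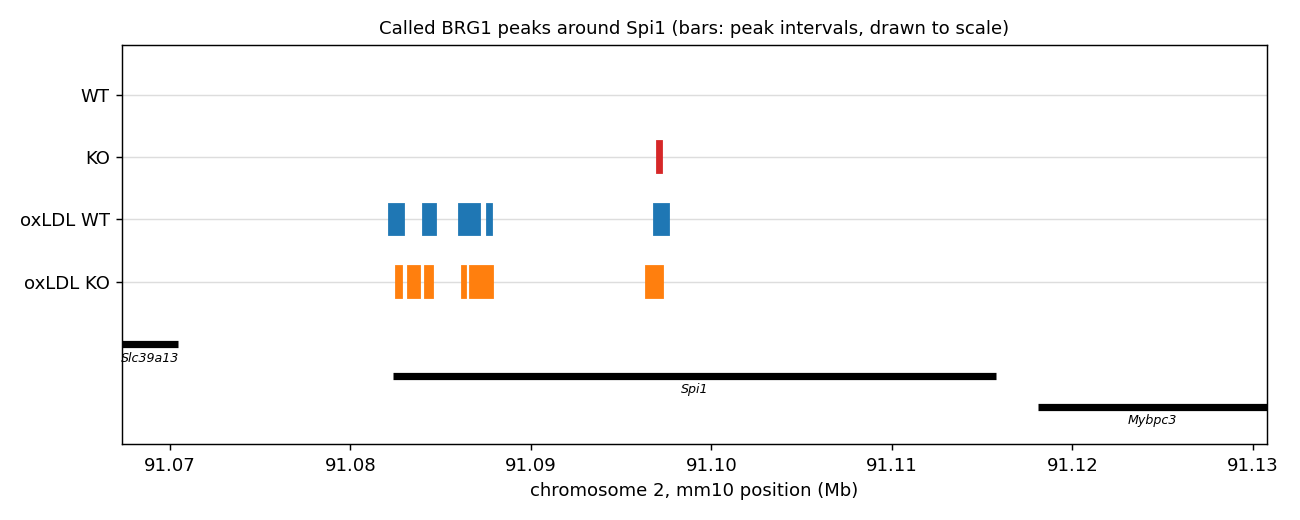
Peaks called in each of the 4 libraries around Spi1 on chromosome 2, from 91067374 to 91130759 of mm10, drawn to scale with protein-coding genes as black bars. The window holds 5 peaks in oxLDL WT, 6 in oxLDL KO, 1 in KO and 0 in WT.

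The highest peaks were shared between genotypes more often than the low ones. Of the 9907 oxLDL WT peaks, 2705 overlapped an oxLDL KO peak by at least 1 bp (27.3%, interval 26.4 to 28.2), and of the 4668 oxLDL KO peaks, 2782 overlapped an oxLDL WT peak (59.6%, interval 58.2 to 61.0). Random placement gave means of 0.168% and 0.360%. With at least 50% of both peaks shared, 16.1% of oxLDL WT peaks were overlapped, and at a −log10 q of at least 5, 18.3%. That limit cuts the lists to 2517 oxLDL WT and 922 oxLDL KO peaks, and the shorter oxLDL KO list limits how many can be overlapped. From the lowest to the highest quintile of oxLDL WT peaks by fold enrichment, the share overlapped was 16.1%, 19.1%, 23.7%, 30.2% and 47.4%. For oxLDL KO peaks it was 44.0%, 51.0%, 57.1%, 64.9% and 81.0%. Pooled over quintiles, peaks at gene ends were overlapped more often than others, with an odds ratio of 1.84 (interval 1.67 to 2.03) for oxLDL WT peaks and 1.33 (1.18 to 1.51) for oxLDL KO peaks. In the highest quintile of oxLDL KO this did not hold against gene bodies, with 80.7% of gene-end peaks overlapped, 86.3% of those inside genes and 73.3% of those outside. Within quintiles of both fold enrichment and width, with summits within 200 bp as the rule, the odds ratios were 1.58 (1.42 to 1.76) and 1.11 (0.980 to 1.26), a test chosen after the data had been seen. Peaks within 1 library are not replicates, so these intervals describe the 2 libraries and not the genotypes.

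**Figure D4:**
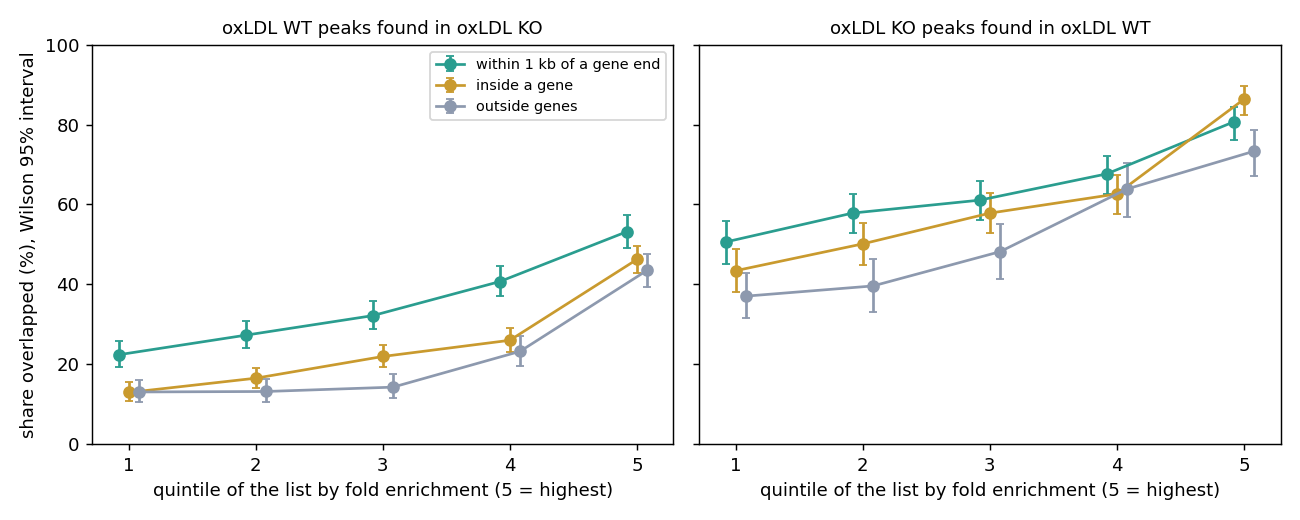
Share of oxLDL WT peaks overlapped by oxLDL KO peaks (left) and of oxLDL KO peaks overlapped by oxLDL WT peaks (right), in percent with Wilson 95% intervals, by quintile of the list ranked on fold enrichment and by the position of the summit. The share over all positions rises from 16.1% to 47.4% (left) and from 44.0% to 81.0% (right).

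The peak with the highest fold enrichment in oxLDL WT that overlapped an oxLDL KO peak lay inside Synpr (chromosome 14, 13361390 to 13362202), at 17.6, with 6.79 in the oxLDL KO list. It was followed by a peak 12 kb from the nearest end of Ifnar1, which encodes a subunit of the type I interferon receptor (chromosome 16, 91521862 to 91523076; 14.7), which was also the highest of the oxLDL KO list, at 11.3. Next came peaks inside Nrp2 (10.9), inside Lcp1, which encodes the leukocyte actin-bundling protein L-plastin (10.7), inside the ceramide kinase gene Cerk (10.3) and at an end of Cables2 (10.3). The other 4 lay nearest to Tmco5 (9.45, at 96.8 kb), Tomm20 (9.38, at 80.8 kb) and Dnajc15 (9.24, at 3.37 kb) and inside Rab14 (9.03). In the oxLDL KO list, the highest shared peaks after that near Ifnar1 lay inside the tyrosine kinase gene Src (chromosome 2, 157447286 to 157447957; 11.0), at Cables2 (10.2) and near Fam187b (10.2). Peaks inside Nod1, an intracellular receptor for bacterial peptidoglycan (8.47), and near Cebpb, a macrophage transcription factor gene (8.15), followed, then Elovl7 (7.92), Lcp1 (7.92), Rab31 (7.69) and Mocos (7.69).

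Of the oxLDL WT peaks with no oxLDL KO counterpart, the highest lay near Rmnd5b (chromosome 11, 51638048 to 51638404; 8.64), inside Tmcc2 (8.19) and Rab20 (8.19), near Prkcq (7.98), inside Plxnb2 (7.77) and Gnaq (7.77), near Ppp1r1c (7.77), and inside the endothelin-converting enzyme gene Ece1 (7.56), the Toll-like receptor gene Tlr6 (7.56) and Cyria (7.52). The highest oxLDL KO peaks with no oxLDL WT counterpart lay near Raet1d (chromosome 10, 22353853 to 22354324; 7.01) and Zfp263 (6.56), inside the kinase gene Ptk2b (6.11), and more than 100 kb from any protein-coding gene end on chromosome 7 (59771296 to 59771736; 6.02). Others, at 5.88, lay inside Abl1, at ends of Kcna3 and Prr14l and near Cox4i1, and 1 lay at an end of Ezh1, which encodes a histone methyltransferase (5.66). The whole comparison rests on 1 library per genotype, and the background level of oxLDL KO was 0.909 times that of oxLDL WT.

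The second comparison set KO against WT without oxLDL. Few BRG1 peaks were called in either genotype, 237 in WT and 139 in KO, and those shared were largely high-background peaks. Of the WT peaks, 45 overlapped a KO peak (19%, interval 14.5 to 24.5), and 39 of these 45 were high-background peaks. Without high-background peaks, 6 of 186 WT peaks were overlapped (3.23%, interval 1.49 to 6.86), and 6 of 91 KO peaks (6.59%, interval 3.06 to 13.6). Random placement gave a mean of 0.00464% for all WT peaks. The share of WT peaks overlapped was 53.6% at a −log10 q of at least 5 and 3.60% with lists of equal length.

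The shared peaks with the highest fold enrichment in WT lay near Tmco5 (5.13 in the WT list), inside Ptpn22, which encodes a lymphoid and myeloid tyrosine phosphatase (chromosome 3, 103859185 to 103859520; 5.13), at an end of Apbb2 (5.13), at an end of Bcl2a1d, a member of an anti-apoptotic gene family (4.59), and at an end of Fnip1, which encodes a folliculin-interacting protein (chromosome 11, 54438237 to 54438536; 4.05). In the KO list these peaks had 3.51, 3.72, 3.48, 3.92 and 4.21. The next 2, near Speer4c (3.50) and Zfp825 (3.18), lay on local backgrounds of 13.0 and 50.3 fragments against the lowest of 2.70, and the last 3 lay at the start of chromosome 9. The highest WT peaks without a KO counterpart lay near Olfr459 (7.30), inside Synpr (6.76), near Ifnar1 (6.49), on chromosome 2 at 117018757 to 117019161 (6.49), near Gm46353 (6.22), inside Rab14 (6.22), at an end of the small GTPase gene Rab1a (5.95), at 2510009E07Rik (5.95), near Capn2 (5.68) and near Ppp1r1c (5.68). The highest KO peaks without a WT counterpart lay near Echdc3 (5.03), inside Tnip1, which encodes an NF-kB pathway inhibitor (4.96), inside Cerk (4.96), and inside Armc7 and Ptk2b (both 4.75). Others at 4.75 lay on chromosome 2 at 128373708 to 128373934, at an end of Wwp1 and inside Kctd13, followed by Gm2974 (4.59) and Lmtk2 (4.54). Gene-end peaks were found at 54 genes in WT and 33 in KO, with 3 genes in both lists. Among the 11 pathway lists, 0 genes had one in WT and 2 in KO, Jund (4.21) and Irf5 (3.79). The other 14 lists had 0 in both. Lists this short cannot show which genes differ between the genotypes.

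The third comparison set oxLDL-treated against untreated WT cells. The oxLDL list was 41.8 times longer than the untreated one. Of the 237 WT peaks, 180 overlapped an oxLDL WT peak (75.9%, interval 70.1 to 80.9), and without high-background peaks 141 of 186 did (75.8%, interval 69.2 to 81.4). This share depends on the rule: it was 39.2% with at least 50% of both peaks shared and 11.0% with lists of equal length. In the other direction, 1.81% of oxLDL WT peaks overlapped a WT peak. Of the 54 genes with a gene-end peak in WT, 44 also had one in oxLDL WT, where independent lists would share 8.04. Recurring WT peaks included those inside Synpr (6.76 in WT), near Ifnar1 (6.49), inside Rab14 (6.22), near Gm46353 (6.22), at Rab1a (5.95) and inside Sh3bp2, an adaptor gene (5.68). WT peaks absent from oxLDL WT were led by the one near Olfr459 (chromosome 6, 41805254 to 41805583; 7.30) and included Cttnbp2nl (5.13), Tox2 (4.86), Soga1 (4.85), a peak on chromosome 6 at 44169755 to 44170123 (4.67), Mapkapk2 (4.59), Ubash3b (4.58), the integrin gene Itga6 (4.50) and Gm51573 (4.40).

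In the oxLDL WT list, the highest peaks that overlapped a WT peak included, beside Synpr, Ifnar1, Nrp2, Cables2, Tmco5 and Rab14, those near the kinase gene Map3k8 (8.40), near Kctd12 (7.77) and Ppp1r1c (7.77), and at an end of Il6ra, the interleukin-6 receptor gene (chromosome 3, 89911601 to 89913653; 7.77). The highest without a WT counterpart were inside Lcp1 (10.7) and Cerk (10.3), near Tomm20 (9.38) and Dnajc15 (9.24), inside Slc15a4, a lysosomal transporter gene (9.03), near Mmp12, the macrophage metalloelastase gene (chromosome 9, 7336959 to 7337212; 9.03), at an end of Ptpn18 (8.82), inside Sla (8.82), at an end of the myeloid tyrosine kinase gene Fes (8.79) and near Rmnd5b (8.64). At one −log10 p minimum for the 4 lists, 5.33, there were 228 WT and 7919 oxLDL WT peaks, a ratio of 34.7. The lowest background was 1.39 times higher in oxLDL WT than in WT.

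The fourth comparison set oxLDL-treated against untreated KO cells. The oxLDL KO list was 33.6 times longer than the KO list, and 97 of the 139 KO peaks overlapped an oxLDL KO peak (69.8%, interval 61.7 to 76.8). Without high-background peaks, 51 of 91 did (56.0%, interval 45.8 to 65.8). With at least 50% of both peaks shared the share was 54.0%, and with lists of equal length 5.76%. Of the 33 genes with a gene-end peak in KO, 23 also had one in oxLDL KO, where independent lists would share 2.89. Recurring KO peaks were led by those inside Tnip1 (chromosome 11, 54933947 to 54934191; 4.96), Cerk (4.96) and Armc7 (4.75), on chromosome 2 at 128373708 to 128373934 (4.75) and at Wwp1 (4.75). Others lay near Fchsd2 (4.54), inside Acvr1b (4.44), at Ppp1r9b (4.40), near Prss56 (4.34) and at Plagl2 and Pofut1 (4.26). KO peaks absent from oxLDL KO were led by Echdc3 (5.03), Ptk2b and Kctd13 (both 4.75), Gm2974 (4.59), Lmtk2 (4.54) and Neurl1a (4.50), and 4 more at 4.34 lay at or in Capn2, Clk4, the integrin gene Itga5 and Ppp1r18.

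In the oxLDL KO list, the highest peaks that overlapped a KO peak lay inside Akna (chromosome 4, 63401366 to 63402250; 7.47) and Ppp1r9b (6.56), near Irf5, an inflammatory transcription factor gene (6.56), inside Nrp2 and Cerk (both 6.34), at Sgk3 (6.16), on chromosome 7 at 59771296 to 59771736 (6.02), inside Armc7 (5.88), at Tbc1d9 (5.88) and at Ripk2, the kinase downstream of NOD receptors (5.66). The highest without a KO counterpart were the 10 named above as the highest oxLDL KO peaks shared with oxLDL WT, from the one near Ifnar1 (11.3) and the one inside Src (11.0) to Rab31 and Mocos (both 7.69). The lowest background of oxLDL KO was 0.890 times that of KO. The change in list length with oxLDL was in the same direction in both genotypes, and whether it differed between them was not tested, with 1 library each.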

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

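Of the tests in this part, those of fold-dependent loss, of immunoprecipitation yield, of the depth of the KO library, of the p limit and of the high-background peaks were chosen after the results had been seen. The differences between untreated and oxLDL-treated cells below were not tested, with 1 library per group.

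Several measures of the lists moved in opposite directions between KO and WT without and with oxLDL. The median peak width in KO minus that in WT was 14 bp without oxLDL and −59 bp with oxLDL. The share of summits outside genes differed by 7.49 percentage points without oxLDL and by −2.40 with it. That reversal rests on high-background peaks: without them, the share was 30.6% in WT, 29.7% in KO, 25.6% in oxLDL WT and 22.6% in oxLDL KO. The number of high-background peaks differed by −3 and 25. The lowest background level differed by 1.14 fragments without oxLDL and by −0.343 with it.

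The shorter oxLDL KO list (4668 peaks against 9907) was set against technical explanations. If the depth of oxLDL KO were the cause, thinning the oxLDL WT pileups to 0.909 of their level would have to leave about as few peaks, but 9255 (SD 19.9) were expected to remain at the p limit of the oxLDL KO list. A loss that depends on fold enrichment alone cannot be told apart from others: oxLDL WT peaks at gene ends were found again more often than others of the same quintile (pooled odds ratio 1.84, interval 1.67 to 2.03), but the counting SD of a fold enrichment, 0.840, exceeds the span of the middle quintile, 0.338. A lower yield of the oxLDL KO immunoprecipitation also stays open and cannot be told apart from an effect of the knockout with 1 library per genotype: 81.0% of the highest quintile of oxLDL KO peaks recurred in oxLDL WT, which either could give.

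The short untreated lists (237 and 139 peaks) were weighed in the same way. Lower depth is argued against in KO, whose lowest background was 1.12 times that of oxLDL KO, and in WT, where 5863 oxLDL WT peaks (SD 37.5) were expected to remain after thinning to 0.718 of their level. A looser p limit in the longer lists is argued against by the common limit, at which oxLDL WT still held 34.7 times as many peaks as WT. A weaker immunoprecipitation in the untreated libraries stays open and cannot be told apart from an effect of oxLDL, because 75.8% of the WT peaks outside high background recurred in oxLDL WT and nothing in the lists measures the yield.

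High-background peaks recurred across conditions. Of the 51 in WT, 35 (68.6%, interval 55.0 to 79.7) were found in all 4 lists, against 3 of the 186 other WT peaks (1.61%), and 29 lay at the start of chromosome 9. The share of high-background peaks found in all 4 lists was 77.1% in KO, 60.3% in oxLDL WT and 42.2% in oxLDL KO. Reads gathered at repeats that are collapsed in the assembly are a candidate explanation for this recurrence, which was least complete in oxLDL KO. Whether BRG1 is also bound at high-background peaks cannot be told apart without values from the input: the median fold enrichment of those in WT was 2.22, against 4.32 for the other WT peaks.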

How the results depend on the processing

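No paired analysis was possible because each group has 1 library, and for the same reason no replicate was left out. Motif searches and random lists matched on GC content were not run, since no genome sequence was used here, and random lists of any protein-coding genes became the main setting. The common p limit, the lists without high-background peaks, gene-length matching, odds ratios within quintiles of width and gene bodies counted with gene ends were chosen after seeing the data. Some results changed order between settings, as given below. A common p limit left all 4 results it applies to within their limits. Counting all contigs or unmerged lines left all 8 and 4 results unchanged. These settings could not change them, since no peak lay on another contig and no peaks of a list overlapped.

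At a −log10 q of at least 5, there were 69 WT, 55 KO, 2517 oxLDL WT and 922 oxLDL KO peaks. The share overlapped became 53.6% for WT by KO, 18.3% for oxLDL WT by oxLDL KO and 87.3% for KO by oxLDL KO. Gene-end shares became 2.90% in WT, 3.64% in KO, 29.4% in oxLDL WT and 36.3% in oxLDL KO, and genes with a gene-end peak 2, 2, 803 and 365. The untreated shares are then near the 3.03% of random positions, and WT by KO exceeds oxLDL WT by oxLDL KO, the reverse of the main setting. Of the peaks left, 45 in WT and 42 in KO were high-background peaks. With at least 50% of both peaks shared, the overlap was 16.1% for oxLDL WT by oxLDL KO, 39.2% for WT by oxLDL WT and 54.0% for KO by oxLDL KO. With summits within 200 bp, it was 20.04% for oxLDL WT by oxLDL KO and 58.2% for WT by oxLDL WT. With lists of equal length, it was 3.60% for WT by KO, 36.5% for oxLDL WT by oxLDL KO, 11.0% for WT by oxLDL WT and 5.76% for KO by oxLDL KO. That setting takes peaks by fold enrichment, and high-background peaks have low fold enrichments. Within 2 kb of a gene end, shares were 28.7% in WT, 41.5% in oxLDL WT and 47.1% in oxLDL KO. Without high-background peaks, KO had 91 peaks, 33.0% of them at gene ends, and the overlap was 3.23% for WT by KO and 56.0% for KO by oxLDL KO.

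For the gene lists, the stricter limit moved 36 of 50 values, gene bodies 4, the 2 kb limit 1 and gene-length matching 4. Matched on gene length, SWI/SNF subunits in oxLDL WT lay at percentile 95.3, cytosolic ribosomal proteins in oxLDL WT at 97.6, and histones at 99.995 in oxLDL WT and 99.85 in oxLDL KO. Their unmatched percentiles were 98.9, 54.9, 36.8 and 33.9, and the cause was not tested. The untreated lists are too short to rank gene lists.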

Other observations

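The test of peak clusters in this part was chosen after the clusters had been seen, and the windows and genes it names were chosen after their values had been seen.

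Some BRG1 peaks under oxLDL lay in dense clusters. Windows of 100 kb were ranked by their number of oxLDL WT peaks, a choice that favours lower numbers in oxLDL KO. The whole oxLDL KO list was also only 0.471 times as long as that of oxLDL WT. The densest window held 16 peaks in oxLDL WT and 7 in oxLDL KO, at Irf2bpl on chromosome 12 (86800001 to 86900000). The window of Zfp36l2, which encodes an mRNA decay factor, held 15 and 8, and that of Sqstm1, which encodes the autophagy receptor p62, held 14 and 6. Windows at the iron storage gene Fth1 and at Nfe2l2 held 12 and 5 each, that of Sirpa, a myeloid inhibitory receptor gene, 12 and 6, that of Mpeg1 12 and 2, that of the Cd300 receptor family 11 and 3, and that of Klf6 11 and 2. Only 3 WT peaks outside high background were found in all 4 lists, at Fnip1, inside Ptpn22 and at Apbb2.

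The window of Thbd, which encodes thrombomodulin, and Cd93, which encodes a surface receptor of myeloid and endothelial cells, held 13 peaks in oxLDL WT and 0 in oxLDL KO (chromosome 2, 148400001 to 148500000). Their fold enrichments ran from 2.81 to 4.62, on pileups of 13 to 21 fragments, and WT held 1 peak there and KO 0. Regional loss of peaks in oxLDL KO may leave such windows, and it would give more windows of 8 or more oxLDL WT peaks with none overlapped by oxLDL KO than chance does. Chance was set by shuffling the overlapped status 10000 times among oxLDL WT peaks of the same quintile of fold enrichment and position class. Of 63 windows with 8 or more peaks, 8 had none overlapped, against a mean of 3.77 in the shuffles, and 3.35% of shuffles had as many. Only 2 of these 8 held no oxLDL KO peak at all, and the other 6 held oxLDL KO peaks that did not overlap, which is not a loss of the whole cluster. Without the window at Cd93, which prompted the test, there were 7, and 7.60% of shuffles had as many. Regional loss therefore stays open, and with 1 library per genotype it cannot be told apart from chance.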
